A study of Rattus norvegicus with 6 samples.

How the data were processed

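Gene expression was measured by poly(A) RNA sequencing in c-kit+ bone marrow cells of 6 rats, 3 per group, 1 library per rat. Per the labels, libraries were made from Trizol-extracted RNA, and cells were selected with a biotinylated antibody and a column-free particle system. The authors' processing is known only in part: the submitters' processing notes name HISAT, GATK and RSEM and the build rn6, with no roles or versions, and other settings are not given in the sources used here. Per the file headers, the authors deposited for each rat an expected count per gene (estimated counts that need not be whole, 72.8% to 74.1% of the listed values being whole) and an FPKM value. Genes without a value in a library are not listed there and were set to 0. The files list 17172 genes, 13876 of them in all libraries, as 13411 Entrez gene IDs and 3761 loci the authors numbered as additional, which hold 6.80% to 8.36% of counts. Symbols came from the authors' table. For list members under other names, a RefSeq gene table of assembly GRCr8 was used, in which 13332 of the 13411 IDs were found, and no coordinates of it are given. The authors' deposited comparison holds the mean FPKM per group, a log2 ratio of PHZ over PBS and a score named Probability. The group means equal the means of the sample files' FPKM within 0.001 in 100% of genes, with 0.01 put for an unlisted gene.

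Expected counts were rounded to whole numbers. The test was edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, glmQLFit with robust estimation, glmQLFTest), with treatment as the only term and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. Standard errors are the absolute log2 fold change over the square root of F. CPM values of tested genes are scaled by TMM, except those of Y-linked and stromal genes given per library, which are per library total, and of Cish where it is set beside the sex labels. Sex was tested in a model with treatment and sex, and the interaction in a model of both. Because the 3 rats of a group are few, p-values rest on 4 residual degrees of freedom, shared over genes by edgeR, with a biological coefficient of variation of 35.2%. Gene lists were fixed before the data were examined: 33 lists, of which 31 were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and the Y-linked and X-linked lists only described. Camera was repeated with an estimated correlation, and fry was run. With an estimated correlation camera tests on the 4 residual degrees of freedom, which raises p whatever the estimate is. Fry tests whether a list's genes move, on balance, one way and does not compare the list with other genes. List scores are the mean over members of log2 CPM (prior count 2), centred per gene. Gene ontology terms of biological processes given in the authors' files, with 10 to 500 genes, were tested with a hypergeometric test among 8436 tested Entrez genes that have such a term (1371 terms).

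The rule for named genes, fixed before the data were examined, took the 10 largest rises and 10 largest falls among called genes with an average log2 CPM of at least 2, groups that do not overlap and a gene symbol that is not a placeholder. It also took from every called list the 3 called members with the smallest p in the list's direction, and always Kit, Epor, Gata1, Gata2, Klf1, Tfrc, Alas2, Hmox1, Cish, Cd34 and Mpo, and for sex the called genes, of which there were none. A result that the rule takes is not reported here. Other genes named as called members complete a count and were chosen after their values were seen.

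Libraries hold 13196249 to 19492793 expected counts. A count of 3 in a library is the limit a count of 0 allows, 0.154 to 0.227 CPM. Such limits cover counting error only. Replicates differed by far more than sampling noise, with a chi-square per degree of freedom of 50.7 to 188 between replicates, so none were merged. Pearson correlations of log2 CPM were 0.911 to 0.951 within PBS, 0.915 to 0.941 within PHZ and 0.872 to 0.917 between groups.

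The tests were tried on simulated data with the real genes' means and dispersions. For PHZ against PBS with 13547 genes, 11 of 100 genes changed 2-fold and 63 of 100 changed 4-fold were recovered, and 5.1% of 78 calls were false. For male against female with 13547 genes the numbers were 4 and 55 of 100, with 20.3% of 74 calls false. No other gene was changed in either, while the real PHZ comparison called 1783 genes. Benjamini-Hochberg adjustment is stricter where few genes change, so 11 and 63 of 100 are not the recovery in the real comparison. Camera called a list raised 1.5-fold in 20 of 20 draws and 0.8% of 600 unchanged lists. In these draws genes varied independently of each other, while the estimated correlation within real lists was as high as 0.87 (stromal and endothelial). The 0.8% therefore does not hold for lists whose members vary together. The term test found 15 of 20 planted terms among 939 drawn genes of 8436, and 1 of 27420 terms in random draws. Genes were drawn independently of each other there too, so the 1 of 27420 does not hold for terms whose genes vary together.

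Alternatives were other scaling (DESeq2 size factors, upper quartile), other tools (DESeq2 1.42.0, limma-voom), no filter, a stricter filter (10 counts in 3 libraries and a mean CPM of 1), limma-trend on log2(FPKM + 1) with FPKM of at least 1 in 3 libraries, on log2(FPKM + 0.1) and without that filter, globins and Alas2 left out, sex as a covariate, the replicate number as a block, and each library left out in turn. Chosen after the data were seen were the fits without the additional loci, without both libraries numbered 1 and without the 3 libraries that go against their sex label.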

Results

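Bone marrow c-kit+ cells were profiled by poly(A) RNA sequencing in 6 ACI rats, 3 injected intraperitoneally with phenylhydrazine (PHZ) at 100 mg/kg and 3 injected with phosphate-buffered saline (PBS). PHZ is a compound that damages red cells and is used to produce haemolytic anaemia. The cells were collected 36 h after injection from rats aged 6 to 8 weeks and were enriched with an antibody to c-kit, the receptor of stem cell factor, which marks haematopoietic stem and progenitor cells and early erythroid cells. Each group held 2 rats labelled female and 1 labelled male. The libraries held 13196249 to 19492793 expected counts each, over 17172 genes and loci, of which 13547 passed the expression filter. Hba1, an alpha globin gene, was the most abundant transcript in all 6 libraries, and globin genes together took from 9.55% of counts in PHZ replicate 1 to 22.0% in PHZ replicate 2. The first comparison asked how the transcriptome of c-kit+ cells differed between PHZ and PBS rats. The libraries labelled male and female were also compared.

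PHZ libraries had far more transcript of 2 genes induced by cytokine receptor signalling in erythroid cells. Cish (Entrez gene 83681), a STAT5-induced inhibitor of cytokine receptor signalling, stood at 55.9 ± 34.0 CPM (SD, n = 3) in PHZ and 1.33 ± 0.21 CPM in PBS libraries, a 41.9-fold rise (edgeR adjusted p = 0.0154). Podxl (Entrez gene 192181), a sialomucin of the cell surface, rose 29.6-fold from 8.85 ± 1.70 to 262 ± 239 CPM (SD, n = 3; edgeR adjusted p = 0.0214), and its PHZ values ran from 100.5 to 536 CPM. Regulators of erythroid differentiation rose by less, with Klf1 2.79-fold and Gata1 2.34-fold higher, and the transferrin receptor gene Tfrc 3.35-fold higher. The transcription factor gene Nfib was lower, and 9 of 18 B lineage genes and 9 of 15 T and NK lineage genes fell. As lists these had adjusted p = 0.0677 and adjusted p = 0.277 with an estimated correlation in camera. The 3 PHZ values and the 3 PBS values did not overlap for Cish, Podxl, Klf1, Gata1, Tfrc and Nfib. The log2 fold change of Podxl was 4.89, and 3.82 without PHZ replicate 1 (edgeR adjusted p = 0.0228).

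Across all genes, 1783 of 13547 were called at an edgeR adjusted p under 0.05, 1218 higher and 565 lower in PHZ (68.3% higher, 58.7% with upper-quartile scaling and 55.1% with DESeq2), and 709 of them differed at least 2-fold, 406 higher and 303 lower. The groups did not overlap in any called gene, and they did not overlap in 41.7% of all genes, against 10% by chance for 3 libraries against 3. The calls depended on single libraries. No gene was called without PBS replicate 2 (3325 at an unadjusted p under 0.05) or without PBS replicate 3 (3291), and 266 and 572 were called without PHZ replicate 2 and PHZ replicate 3. All 1783 genes kept their direction in each of these 4 fits. That adds no support, since groups that do not overlap keep their direction whichever library is left out, apart from small changes in scaling. With sex as labelled as a covariate 928 genes were called, and with the 3 libraries left out whose Y-linked transcripts go against their sex label, which leaves 1 PBS and 2 PHZ libraries, edgeR called 0 genes (1480 at an unadjusted p under 0.05).

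The 10 largest rises, by the rule fixed beforehand, also included Trim15 (34.3-fold), which encodes a tripartite motif protein, Pdzk1ip1 (21.6-fold), and Clcn2 (20.8-fold), a chloride channel gene. Clcn2 was among the steadiest of them, at 108 ± 9.80 CPM in PHZ and 5.17 ± 1.85 CPM in PBS libraries (SD, n = 3; edgeR adjusted p = 0.0154). Mylk3 rose 16.7-fold, Gpr4, a proton-sensing receptor gene, 14.7-fold, Myl6b, which encodes a myosin light chain, 13.8-fold and Actr3b 10.7-fold. Alox15, the lipoxygenase that acts on organelle membranes of maturing reticulocytes, started at a much higher level and rose 6.91-fold, from 250.4 ± 55.7 to 1729 ± 748 CPM (SD, n = 3; edgeR adjusted p = 0.0169). The plot of selected genes shows these values per library.

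**Figure D1:**
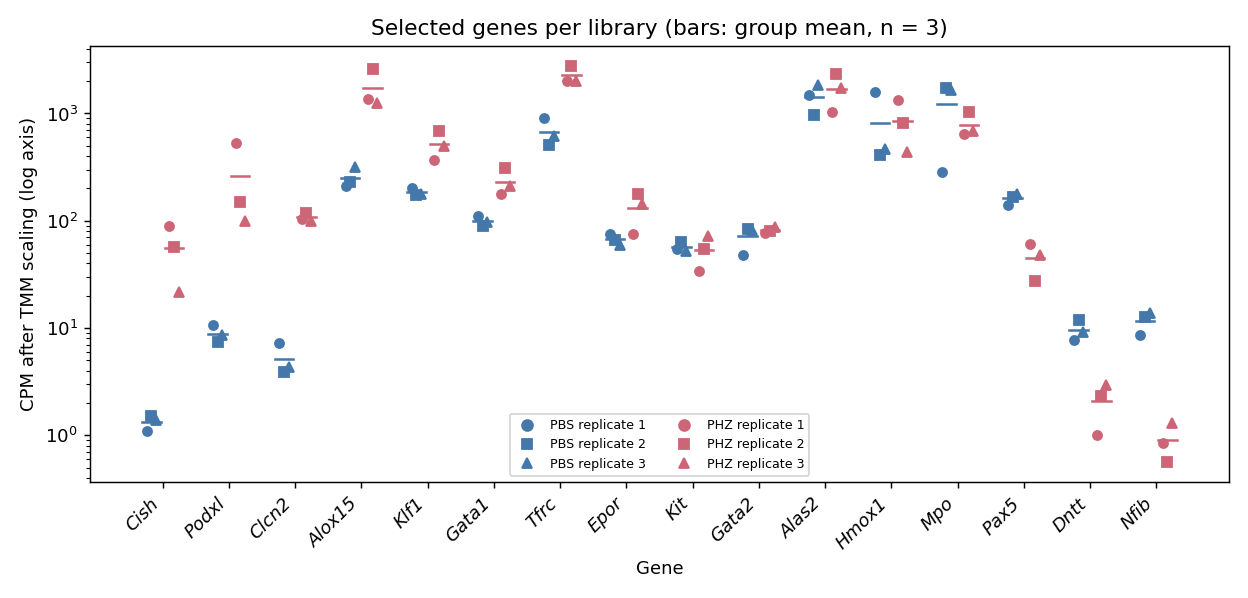
CPM after TMM scaling of 16 genes in each library, on a log axis, with points for the 3 PBS and 3 PHZ replicates and bars for the group means. Cish lies between 21.5 and 89.4 CPM in PHZ and between 1.09 and 1.51 CPM in PBS libraries, while the 2 groups overlap for Epor, Kit, Gata2, Alas2, Hmox1 and Mpo.

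Of 19 genes of haem synthesis and iron uptake, 12 rose, none fell and 7 were not called (17 rose when adjusted over the list alone). Cpox, coproporphyrinogen oxidase, rose 3.50-fold from 244 ± 52.3 to 853 ± 197 CPM (SD, n = 3; edgeR adjusted p = 0.0175), Steap3, the ferrireductase of transferrin endosomes, 3.46-fold and Abcb10, a mitochondrial transporter, 2.52-fold. Camera gave the list an adjusted p of 1.09e-15, and adjusted p = 0.366 with an estimated correlation. Alas2, the first enzyme of erythroid haem synthesis, was not called, at 1431 ± 446 CPM in PBS and 1698 ± 642 CPM in PHZ libraries (SD, n = 3; edgeR adjusted p = 0.658). Of 23 red cell membrane and surface genes, 13 rose and 10 were not called (19 rose when adjusted over the list alone). Those with the smallest p were the carbonic anhydrase gene Car1 (3.11-fold), the ankyrin gene Ank1 (2.32-fold) and Xk (1.83-fold; camera adjusted p = 5.69e-13, and adjusted p = 0.366 with an estimated correlation). Of 18 erythroid transcription factor genes, 8 rose and 1 fell (9 and 1 when adjusted over the list alone). The rises included E2f4 (2.98-fold), Zfpm1 (2.74-fold), the cofactor of GATA1, and Klf1, and the gene that fell was Cbfa2t3 (camera adjusted p = 6.56e-05, and adjusted p = 0.366 with an estimated correlation).

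The globin list was not called. Of 9 members 8 had a higher estimate in PHZ and 2 rose, Ahsp, the alpha globin chaperone, and Hbg1, which had 0.766 to 1.25 CPM in PHZ libraries, and 7 were not called (2 rose when adjusted over the list alone; camera adjusted p = 0.123, and adjusted p = 0.555 with an estimated correlation). Some globin genes are near-identical copies. How the authors' counting divided reads among such copies is not known, so their single values are uncertain. Hba1 stood at 95930 ± 46350 CPM in PBS and 110500 ± 58480 CPM in PHZ libraries (SD, n = 3), a difference within the spread between rats. Of 15 genes of the erythropoietin signalling list only Cish and Podxl were called, over all genes and when adjusted over the list alone. The list's median log2 fold change was -0.36 while its mean was 0.61 (camera adjusted p = 0.438, adjusted p = 0.523 with an estimated correlation, and fry adjusted p = 0.0437, higher in PHZ). The erythropoietin receptor gene Epor had 67.0 ± 8.17 CPM in PBS and 132 ± 52.2 CPM in PHZ libraries (SD, n = 3; edgeR adjusted p = 0.0792), and it was called by DESeq2 (adjusted p = 0.0176) and without PHZ replicate 1 (edgeR adjusted p = 0.023; 0.0176 to 0.22 over its 12 alternatives). Without PHZ replicate 1 camera also called the erythropoietin signalling list (adjusted p = 0.0239) and the globin list (0.0239), and without PBS replicate 3 the globin list (0.0236), all higher in PHZ, as was the globin list without both libraries numbered 1 (0.0463).

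Of 25 G1/S and DNA replication genes, 24 rose and 1 was not called (25 rose when adjusted over the list alone). The examples are Ccne1, cyclin E1 (3.11-fold), the helicase subunit gene Mcm6 (2.58-fold, from 131 ± 2.71 to 339 ± 55.4 CPM, SD, n = 3; edgeR adjusted p = 0.0154) and Uhrf1 (2.17-fold). Camera gave the list an adjusted p of 8.45e-28, and adjusted p = 0.278 with an estimated correlation. Of 22 G2/M and mitosis genes, 14 rose and 8 were not called (22 rose when adjusted over the list alone), among them Ccnb1 (2.55-fold), Ccna2 (2.11-fold) and Cdc20 (1.96-fold; camera adjusted p = 1.16e-12, and adjusted p = 0.366 with an estimated correlation). Of 24 MYC and ribosome biogenesis genes 9 rose, among them Cad (2.03-fold), Fbl (1.75-fold) and Nop2 (1.69-fold; 20 rose when adjusted over the list alone; camera adjusted p = 1.79e-07, and adjusted p = 0.366 with an estimated correlation). Of 26 oxidative phosphorylation genes 10 rose, with the smallest p for Ndufs1 (1.81-fold), Cyc1 (1.89-fold) and Uqcrc1 (1.73-fold; 19 rose when adjusted over the list alone; camera adjusted p = 2.58e-09, and adjusted p = 0.366 with an estimated correlation).

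Of 14 heat shock genes 4 rose, the mitochondrial chaperonin genes Hspd1 (2.20-fold) and Hspe1, Hsph1 (2.32-fold) and Hsp90aa1 (1.95-fold; 6 when adjusted over the list alone; camera adjusted p = 0.000565, and adjusted p = 0.414 with an estimated correlation). Of 24 antioxidant and NRF2 genes 8 rose, over all genes and when adjusted over the list alone, with the smallest p for the biliverdin reductase gene Blvrb (2.36-fold), the glutathione synthesis gene Gclc (1.98-fold) and Srxn1 (2.24-fold; camera adjusted p = 0.00179, and adjusted p = 0.366 with an estimated correlation). Hmox1, haem oxygenase 1, had 818 ± 651 CPM in PBS and 857 ± 447 CPM in PHZ libraries (SD, n = 3; edgeR adjusted p = 0.948). The log2 fold change of Hmox1 was 0.07, and it ran from -0.39 without PHZ replicate 1 to 0.96 without PBS replicate 1, the PBS library with the highest value (1569 CPM). Of 21 cholesterol synthesis genes 2 rose, over all genes and when adjusted over the list alone, Sqle (2.41-fold) and Fdps (2.09-fold; camera adjusted p = 0.0133, adjusted p = 0.523 with an estimated correlation, and 0.123 without PHZ replicate 1). Of 19 p53 response genes 1 fell, over all genes and when adjusted over the list alone, the ribonucleotide reductase gene Rrm2b (1.72-fold lower; camera adjusted p = 0.0465, adjusted p = 0.366 with an estimated correlation, and 0.145, 0.0622 and 0.0986 without PBS replicate 1, PHZ replicate 2 and PHZ replicate 3). The unfolded protein and integrated stress response list was not called, with 3 genes that rose, Asns, Psat1 and Eif2ak1, and Ddit3, which fell (camera adjusted p = 0.787; 4 and 2 when adjusted over the list alone). The hypoxia and glycolysis list had 1 called gene of 26, the glucose transporter gene Slc2a3, which fell, over all genes and when adjusted over the list alone. Its median log2 fold change was 0.27 and its mean 0.14. Camera's nominal direction for it was lower, but camera did not separate it from the other genes (adjusted p = 0.939). The autophagy list had 1 called gene of 20, Tfeb, which fell, over all genes and when adjusted over the list alone, and a median of -0.09 with a mean of 0.01 (camera adjusted p = 0.787). No gene of 12 in the glucocorticoid response list was called (0 when adjusted over the list alone; camera adjusted p = 0.239).

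Of 18 B lineage genes 9 fell and 9 were not called (11 fell when adjusted over the list alone), with a median log2 fold change of -1.57. Pax5, the transcription factor of B cell commitment, was 3.59-fold lower, at 45 ± 16.7 CPM against 162 ± 20.1 CPM (SD, n = 3; edgeR adjusted p = 0.0215), Blnk 3.21-fold lower and the receptor component gene Cd79b 3.04-fold lower. Camera gave the B lineage list an adjusted p of 4.1e-12, and adjusted p = 0.0677 with an estimated correlation. The estimate was 0.01, the same as the preset, so the higher p does not come from a larger correlation of its members. It comes with the 4 residual degrees of freedom on which camera tests when it estimates the correlation. Of 15 T and NK lineage genes 9 fell and 6 were not called (13 fell when adjusted over the list alone), among them Cd3e (9.06-fold lower), Cd5 (5.24-fold lower) and Cd8a (2.65-fold lower), at low levels of 6.29 ± 3.33, 5.41 ± 1.08 and 11.7 ± 2.14 CPM in PBS libraries (SD, n = 3). Camera gave this list an adjusted p of 7.94e-08, and adjusted p = 0.277 with an estimated correlation. Among the 10 largest falls of single genes, Nfib was 13-fold lower, at 11.8 ± 2.71 CPM in PBS and 0.91 ± 0.37 CPM in PHZ libraries (SD, n = 3; edgeR adjusted p = 0.0154). Vpreb2, a surrogate light chain gene of early B cells, was 8.17-fold lower and Dntt, the terminal transferase gene of early lymphocytes, 4.64-fold lower. Plxnd1 was 5.10-fold lower, Nup210l 5.42-fold, Aff3 4.64-fold and Nos2, inducible nitric oxide synthase, 4.37-fold.

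Of 18 stem and early progenitor genes 3 fell, Procr (4.33-fold lower), Fli1 (1.99-fold) and Thy1 (2.85-fold; 4 when adjusted over the list alone; camera adjusted p = 0.00221, and adjusted p = 0.277 with an estimated correlation). Kit, whose product was used for the selection, stood at 56.8 ± 6.32 CPM in PBS and 53.5 ± 18.9 CPM in PHZ libraries (SD, n = 3; edgeR adjusted p = 0.841), and Gata2 at 71.5 ± 20.3 and 81.6 ± 5.75 CPM (edgeR adjusted p = 0.583). Cd34 did not pass the expression filter and was not tested. Of 18 late neutrophil granule genes, Retnlg (1.90-fold lower) and Olfm4 (1.49-fold lower) fell (1 when adjusted over the list alone; camera adjusted p = 4.26e-05, and adjusted p = 0.421 with an estimated correlation). No gene of 13 in the primary granule list was called (0 when adjusted over the list alone; camera adjusted p = 0.0534, adjusted p = 0.543 with an estimated correlation, and 6.77e-07 and 0.0334 without PBS replicate 1 and PHZ replicate 2). Mpo had 1219 ± 809 CPM in PBS and 786 ± 209 CPM in PHZ libraries (SD, n = 3; edgeR adjusted p = 0.517, and 0.0444 and lower in PHZ without PBS replicate 1; 0.0444 to 0.819 over its 12 alternatives). Of 16 megakaryocyte genes, Thbs1 (1.55-fold lower) and Plek (1.49-fold lower) fell, over all genes and when adjusted over the list alone (camera adjusted p = 0.00259, adjusted p = 0.376 with an estimated correlation, and 0.0962 without both libraries numbered 1). The mast cell, basophil and eosinophil list was called with no gene of 18 past the threshold (0 when adjusted over the list alone; camera adjusted p = 0.00167, and adjusted p = 0.313 with an estimated correlation). The same held for the monocyte and macrophage list (0 of 20 genes, 0 when adjusted over the list alone; camera adjusted p = 0.0409, adjusted p = 0.555 with an estimated correlation, and 0.9, 0.189 and 0.056 without PBS replicate 1, PHZ replicate 2 and PHZ replicate 3) and for the dendritic cell and MHC class II list (0 of 12 genes, 0 when adjusted over the list alone; camera adjusted p = 0.0102, adjusted p = 0.523 with an estimated correlation, and 0.117 without PBS replicate 1).

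Of 16 immediate early genes 4 fell, Jund, Dusp2 (3.36-fold lower), Fosb (2.57-fold) and Cyr61 (2.54-fold; 6 when adjusted over the list alone; camera adjusted p = 3.13e-05, and adjusted p = 0.366 with an estimated correlation). Of 26 interferon response genes 5 fell and 1 rose, Cmpk2, with Ifit3 2.65-fold, Oasl 2.47-fold and Ifit2 1.93-fold lower (6 and 1 when adjusted over the list alone; camera adjusted p = 0.00167, adjusted p = 0.421 with an estimated correlation, and 0.113 without the 3 libraries against their sex label). Nfkb2 was the 1 called gene of 17 in the inflammatory list, over all genes and when adjusted over the list alone (2.07-fold lower; camera adjusted p = 0.00376, and adjusted p = 0.498 with an estimated correlation). Of 13 BMP and TGF-beta genes Id3 (3.81-fold lower) and Smad7 (2.02-fold lower) fell, over all genes and when adjusted over the list alone (camera adjusted p = 0.0132, adjusted p = 0.366 with an estimated correlation, and 0.0824 without the 3 libraries against their sex label). Stromal and endothelial genes were lower as a list, with Kdr (6.84-fold lower) the 1 called gene of 11 (1 when adjusted over the list alone; camera adjusted p = 0.0065, adjusted p = 0.523 with an estimated correlation, and 0.0827 without PBS replicate 1). The log2 fold change of Kdr was -2.77, and -1.89 without PBS replicate 1 (edgeR adjusted p = 0.0401). In PBS replicate 1 the stromal score was 3.66 and in the other 5 libraries it lay between -1.82 and -0.13 (log2 units). PBS replicate 1 also had the highest monocyte and macrophage score, 0.85, and the highest MHC class II score, 1.04. Camera called 24 of 31 lists, 10 higher and 14 lower, and with an estimated correlation it called 0 (fry called 17). Other splits of the same 6 libraries into 3 and 3 gave up to 20 called lists with the preset correlation.

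**Figure D2:**
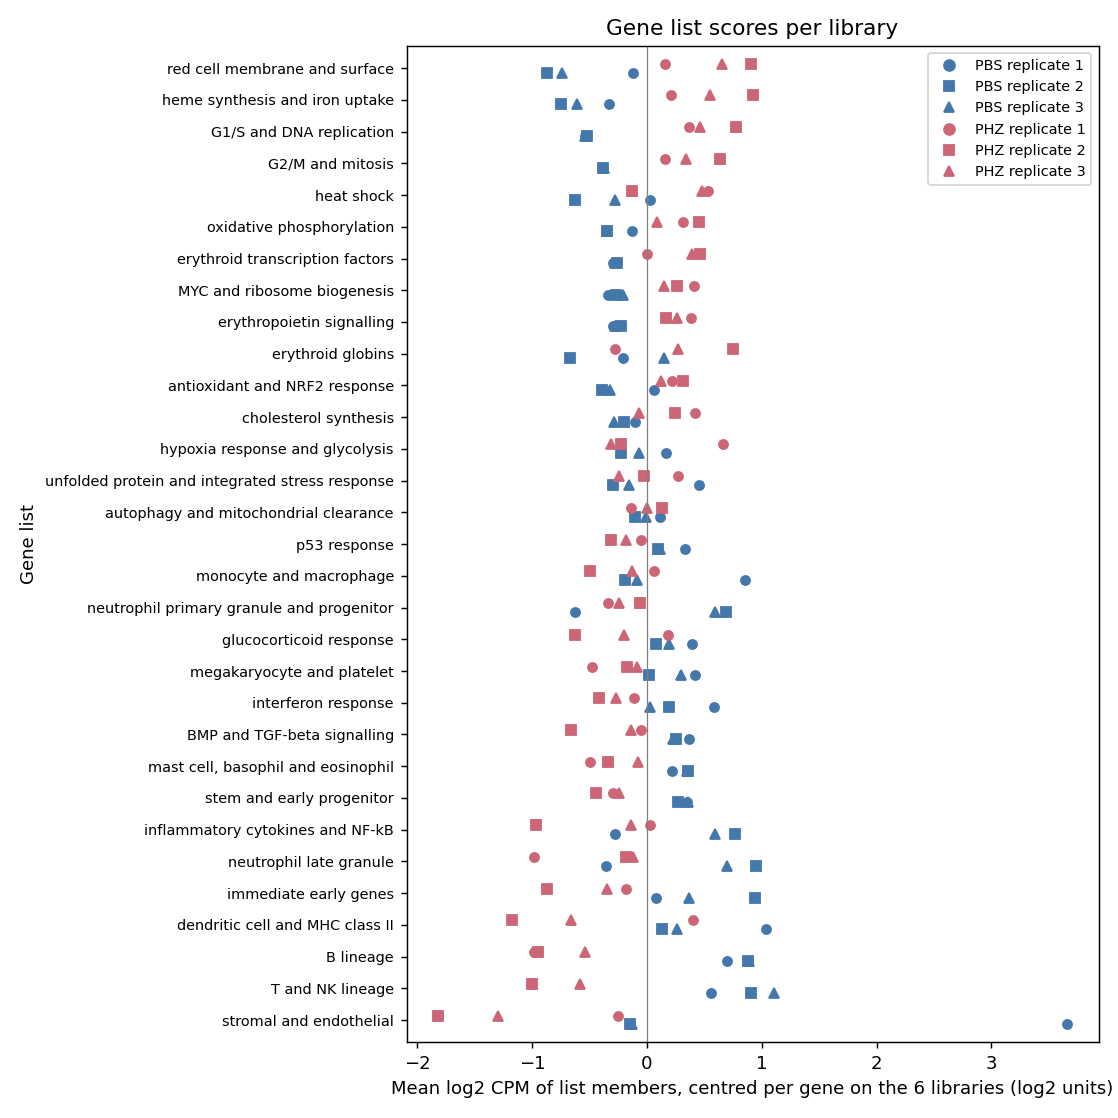
Mean log2 CPM of the members of each of 31 gene lists per library, centred per gene on the 6 libraries, with points for the 3 PBS and 3 PHZ replicates. The B lineage score lies between 0.70 and 0.89 in PBS and between -0.98 and -0.54 in PHZ libraries, while the stromal score is 3.66 in PBS replicate 1 alone.

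The authors' deposited table of the same comparison marks 546 genes Up and 1183 Down in PHZ. Each gene marked in the authors' deposited table has a probability of at least 0.802 and an absolute log2 ratio of at least 1. The calls here at an adjusted p under 0.05 have no such fold limit. Most marks are Down, whereas of the 709 genes called here with at least a 2-fold change 406 were higher and 303 lower. Of the 1604 marked genes of the authors' deposited table that were tested here, all 1604 had the same sign in edgeR. Of these, 634 were called, 338 higher and 296 lower. The shared sign adds no support, since both comparisons use the same libraries and a mark needs at least a 2-fold ratio. Of the 709 genes called here with at least a 2-fold change, 612 are marked in the authors' deposited table. The authors' deposited table gives Cish a mean of 0.74 FPKM in PBS and 30.6 FPKM in PHZ rats, a log2 fold change of 5.37.

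The libraries labelled male and female were then compared. Neither the sex effect nor its interaction with treatment gave a called gene in edgeR (0 of 13547 each, with 379 and 633 genes at an unadjusted p under 0.05) or in limma-voom (0 each, with 417 and 587). The Y-linked genes did not follow the sex labels. Ddx3y, a Y-linked RNA helicase gene, had 149 CPM in PBS replicate 1 and 106 CPM in PHZ replicate 3, both labelled female, and 87.8 CPM in PHZ replicate 2, labelled male. Eif2s3y had 61.1, 55.4 and 49.0 CPM in the same libraries. Both genes had 0 counts in PBS replicate 2, labelled male, and in PBS replicate 3 and PHZ replicate 1, labelled female. A count of 0 allows up to 0.184 CPM in PBS replicate 2. So 3 of 6 libraries went against their label, and the 3 libraries with Y-linked transcripts were 1 of 3 PBS and 2 of 3 PHZ libraries. No direction is drawn from the comparison of the sexes. Cish separated the PHZ from the PBS libraries in all 6.

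**Figure D3:**
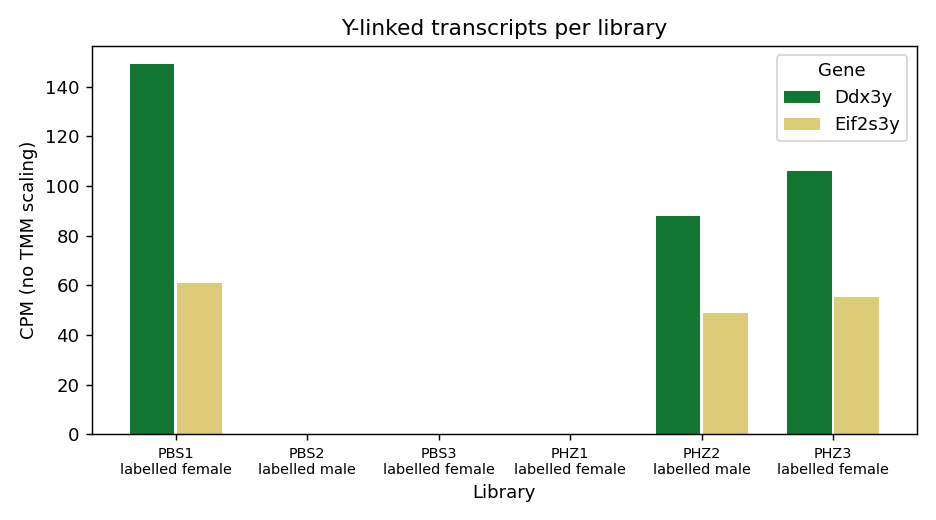
CPM of the Y-linked genes Ddx3y and Eif2s3y in each of the 6 libraries, with the sex given by the labels under each library. Both are present in PBS replicate 1, PHZ replicate 2 and PHZ replicate 3 and have 0 counts in the other 3 libraries.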

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

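The tests of the sex labels were chosen after the values were seen. Y-linked transcripts were present in libraries labelled female. Their list was described and is not among the 31 gene lists tested. Ddx3y had 149 CPM in PBS replicate 1 and 106 CPM in PHZ replicate 3, and Eif2s3y had 61.1 and 55.4 CPM, against 0 counts of both in PBS replicate 3 and PHZ replicate 1, which are also labelled female. A locus that the authors assembled, with its best protein match in the Y-linked demethylase KDM5D, had 44.4, 51.7 and 51.6 CPM in PBS replicate 1, PHZ replicate 2 and PHZ replicate 3 and 0 in the other libraries.

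Reads of the X copy counted on the Y copy are argued against by PHZ replicate 1, which had 9688 counts of Ddx3x, the highest of the 6 libraries, and 0 counts of Ddx3y and Eif2s3y. An exchange of libraries between PBS and PHZ is argued against by Cish, whose lowest PHZ value was 13.3 times its highest PBS value in CPM without TMM scaling (21.2 against 1.60). Sex labels that do not belong to the libraries stay open and were not tested apart from the pattern itself, the 3 libraries that went against their label. An exchange between PBS replicates 1 and 2 would leave PHZ replicate 3 unexplained, since 3 libraries have these transcripts and the labels give 2 males. Which records are wrong stays open, and no biological explanation was tested.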

How the results depend on the processing

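The fits without both libraries numbered 1 and without the 3 libraries that go against their sex label were chosen after the data were seen, as was the fit without the additional loci. In every setting each gene called in PHZ against PBS that could be tested kept its direction, but the number of calls moved. Where libraries were left out, the kept direction adds no support, since the groups do not overlap in any called gene. DESeq2 called 3476 genes (1142 of them at least 2-fold) and limma-trend on FPKM without a filter 866 (332). Sex as labelled as a covariate gave 928 calls (468), and the fit without both libraries numbered 1 gave 2920 (1451). The labels go against the Y-linked transcripts in 3 libraries, so this covariate does not adjust for the sex those transcripts show. With the replicate number as a block 0 genes were called (0 at least 2-fold; edgeR, 4641 at an unadjusted p under 0.05), on 2 residual degrees of freedom. Deviations from the group means correlated by 0.213, 0.057 and 0.005 between libraries of the same number. Not every library correlated best with its own number (PBS replicate 3 with PHZ replicate 2, 0.154), so the numbers were not taken to pair the rats. The libraries numbered 1 did stand together. On the second principal component of log2 CPM (24.3% of variance) PBS replicate 1 lay at 52.6 and PHZ replicate 1 at 52.8. The other libraries lay between -36.9 and -6.6. PBS replicate 1 correlated by 0.917 with PHZ replicate 1, and by 0.911 and 0.916 with PBS replicates 2 and 3. A factor shared by the libraries numbered 1 stays open. Without the 3 libraries against their sex label edgeR called 0 genes (0 at least 2-fold; 1480 at an unadjusted p under 0.05), with 1 PBS library assumed to vary like the PHZ libraries. Leaving out each library in turn gave 0 (without PBS replicate 2 or 3) to 1744 calls (without PBS replicate 1), and 0 to 881 with at least 2-fold change. The cause of these moves was not tested, beyond fewer libraries in the fits that leave some out. Other scaling, filters, limma-voom, FPKM pseudocounts, globins left out and additional loci left out gave 1474 to 2491 calls. Of 79 named genes, DESeq2 lost no call, limma-voom lost 5, and sex as labelled as a covariate 18. Without PBS replicate 2, 73 were lost, and 73 without PBS replicate 3.

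Camera called 0 of 31 lists with the correlation estimated per list. The estimates ran from -0.03 (erythropoietin signalling) to 0.87 (stromal and endothelial). For the B lineage list the estimate equalled the preset 0.01, so a larger correlation does not explain every lost call. This setting also tests on 4 residual degrees of freedom, so its lost calls do not measure correlation alone. Without the 3 libraries against their sex label 18 of the 24 called lists kept their call, and BMP and TGF-beta (adjusted p = 0.0824), interferon (0.113), MHC class II (0.158), p53 (0.263), stromal (0.263) and monocyte (0.602) lost it. Without both libraries numbered 1 20 kept it, and p53 (0.072), megakaryocyte (0.0962), cholesterol (0.17) and monocyte (0.31) lost it. The primary granule list gained a call in both (3.37e-05 and 2.86e-05) and with sex as a covariate (0.0489). Results that reversed were not called in any of these fits. The hypoxia list turned with fry (adjusted p = 1), with the replicate block (0.856), without the 3 libraries against their sex label (0.358) and without single libraries (0.105 to 0.929 over these). The autophagy list turned without the 3 libraries (0.841), without both numbered 1 (0.556) and without single libraries (0.484 to 0.991), and the unfolded protein list without the 3 libraries (0.263) and without single libraries (0.263 to 0.789). Over fits without single libraries the log2 fold change ran from -0.34 to 0.16 for Kit, -0.03 to 0.32 for Gata2, -0.04 to 0.51 for Alas2 and -0.39 to 0.96 for Hmox1. Depth limits genes with low counts, where a count of 0 allows 0.154 to 0.227 CPM.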

Other observations

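Among gene ontology terms, 39 were over-represented among the genes that rose and 21 among those that fell. The hypergeometric test treats genes as independent, so terms whose genes vary together are called too readily. Beyond replication and mitosis, 9 of the 11 genes of 'de novo' protein folding rose against 1.22 expected (hypergeometric test, adjusted p = 3.1e-05). The subunits of the CCT chaperonin, which folds actin and tubulin, rose together, with Cct6a 1.99-fold, Tcp1 1.90-fold, Cct8 1.82-fold, Cct7 1.71-fold, Cct3 1.66-fold, Cct4 1.52-fold, Cct5 1.51-fold and Cct2 1.47-fold higher (edgeR adjusted p of 0.019 to 0.0487). Of 117 genes of translation 27 rose against 13 expected (adjusted p = 0.0127), of 30 of mitochondrial translation 11 against 3.34 (adjusted p = 0.0135) and of 10 of proteasome assembly 6 against 1.11 (adjusted p = 0.014). Among the falls, 10 of 23 genes of B cell receptor signalling (adjusted p = 4.52e-05), 10 of 42 of T cell receptor signalling (adjusted p = 0.00431) and 17 of 117 of cell migration (adjusted p = 0.00633) were found. The genes and terms of this paragraph were chosen after their values were seen.

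Of the tests below, those of dilution, of the selection and of the libraries numbered 1 were chosen after the values were seen. B lineage and T and NK lineage members were lower in PHZ libraries. Dilution by a larger share of other transcripts would lower the markers of the other lineages alike. The score of B and T members minus that of 6 other lists (primary granule, late granule, monocyte, mast cell, megakaryocyte and MHC class II) was 0.54 ± 0.15 in PBS and -0.54 ± 0.15 in PHZ libraries (SD, n = 3). This difference of -1.07 log2 units, with no overlap, argues against dilution as the whole cause. All 6 other lists were lower in PHZ too, with score differences of -0.38 to -0.96, against -1.64 (B lineage) and -1.72 (T and NK lineage). The B and T lists fell most of these, so choosing them after their values were seen adds to the difference. With the stromal list, which is high in PBS replicate 1, added to the others the difference was -0.90, and -0.83 with each list weighted equally, where the groups came as near as -0.11 in PBS replicate 1 and -0.18 in PHZ replicate 3. The pattern does not rest on PBS replicate 1, since without it both lists stayed called with the preset correlation (the higher camera adjusted p was 2.51e-08), a call that neither list has over all 6 libraries with an estimated correlation (adjusted p = 0.0677 for B lineage, and adjusted p = 0.277 for T and NK lineage). Each rat had 1 selection, so fewer c-kit-negative cells carried over in PHZ rats and fewer lymphoid cells in the marrow cannot be told apart. Lists of mature cells fell too, but by less than the B and T lists (medians of -1.57 and -1.92). The MHC class II list had a median of -0.98 (camera adjusted p = 0.0102, and adjusted p = 0.523 with an estimated correlation). That list is highest in PBS replicate 1 and was not called without it (camera adjusted p = 0.117). The late granule list had a median of -0.93, with 18 of 18 members lower (camera adjusted p = 4.26e-05, and adjusted p = 0.421 with an estimated correlation). Its score of -0.36 in PBS replicate 1 was the lowest of the PBS libraries, and it kept its call without that library.

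Stromal transcripts were high in PBS replicate 1, with Cxcl12 at 372 CPM against 1.39 to 8.80 CPM in the other libraries and Col1a1 at 77.3 CPM against 0.303 to 9.22. A second list of 25 stromal genes was written before their values were seen, and none of its members is in another list. Of its 18 members with at least 10 counts, 15 had their highest CPM in PBS replicate 1, among them Igfbp7 (35.0 CPM) and Bgn (17.1 CPM), which is consistent with stromal cells carried into that library, although the c-kit selection would be meant to remove them. The exceptions were Alpl, Fn1 and Serpinf1. A condition shared by the libraries numbered 1 may add to it, since 13 of 19 stromal genes were highest among PHZ libraries in PHZ replicate 1, but Cxcl12 and Lepr were not, and many of these values are near the counting limit. No biological explanation was tested.

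Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called 1783 genes, 709 of them 2-fold, and the highest other split 7 genes, all 2-fold. For gene lists the real split called 24, and the other splits called 9 to 20 with the preset correlation. Each other split mixes the treatments unequally between its groups, so part of the treatment difference stays in it. These counts are therefore not a rate of calls without a treatment effect.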
